A study of Mus musculus with 6 samples.

How the data were processed

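Gene expression was measured in mammary tumours of 16-week-old mice carrying the polyoma middle T oncogene (PyMT), a transgene that drives tumours of the mammary epithelium. Per the labels, 3 tumours came from mice with an intact Slc6a14 gene (WT/PyMT, called wild type here) and 3 from mice in which Slc6a14 was deleted (Slc6a14-KO/PyMT, called knockout here), all on a C57BL/6 background. The series describes the 3 tumours of each group as biological replicates. Total RNA was extracted with Trizol and turned into biotinylated cDNA with a whole-transcript kit for Affymetrix GeneChip arrays, 1 array per tumour, per the labels' protocols. Whole tumour pieces were profiled, so each value is an average over tumour cells and the other cell types in the piece.

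The deposited table holds 1 log2 value for each of 41345 probe sets on each of the 6 arrays. Partek is named in the submitters' processing notes, without a version or a role, and the background correction, probe summarization and normalization are not given in the sources used here. The values already lay on 1 scale: array medians ran from 5.69 to 5.74, and array maxima from 14.76 to 14.90. They were used as deposited. Compression of low signals by the background step would shrink the differences of dim genes, and array values carry no read depth. The number of arrays limits the precision.

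Probe sets were named through the platform annotation. It gave 1 gene for 23521 probe sets and several genes for 1814, and 16010 probe sets are unnamed here. Of the single-gene probe sets, 23328 matched a gene of the mouse RefSeq table by gene ID, and 0 symbols needed an update. No gene was named from a probe set with several genes. This left 22180 genes, of which 1082 had more than 1 probe set and were represented by the one with the highest mean over the 6 arrays. Among the genes named by the rule or held by a list, 34 had several probe sets, and those of 6 went in opposite directions (Car9, Ckm, Gm5124, Ryr1, Slc2a1 and Slc7a11). Others differed in size, Cdh2 (1.22 and 0.42), Ccdc80 (0.63 and 0.21) and Lpl (0.50 and 0.044) among them. A further property of the table is that 1395 probe sets, in 593 groups, had values identical to another probe set in all arrays. No genome build is given for the array in the sources used here, so coordinates are not printed, and the RefSeq table served only for names and for which genes lie near each other.

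Knockout and wild-type tumours were compared with limma (version 3.58.1, in R 4.3.3), using lmFit and eBayes with a constant prior, two-sided, over all 41345 probe sets. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. All adjusted p-values for genes come from this fit unless stated. Differences are knockout minus wild type on the log2 scale with the standard error (SE) of the fit, and group levels are mean ± SD with n = 3. An exact permutation test of 3 against 3 cannot give a p below 0.1 and was not used for single genes.

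A set of 27 gene lists was fixed before the data were examined. They cover amino acid transport and its response programmes, growth and metabolism, the mammary epithelium, the other cell types a tumour piece can hold, and signs of handling, time of day and sex. Lists were tested with limma's camera, which asks whether the genes of a list shift relative to all other genes, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. Beside it stand camera with the correlation estimated from the arrays, and limma's fry, which asks whether a list's genes move one way on balance. The genes within 5 Mb of Slc6a14 on the X chromosome formed a separate set.

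The rule for named genes was also fixed before the data were examined. It takes Slc6a14, then in each direction the 13 genes with the largest differences among those past the threshold whose groups do not overlap. Places left open are filled by genes with an unadjusted p under 0.01 and no overlap. Genes known only by a clone name, olfactory and vomeronasal receptor genes, and segments of antigen receptor genes were passed over. Up to 4 members of each list, those with the smallest p, were named as well. Genes with near-identical copies can share probes, so values of Snora73a and Snora73b, Lyz1 and Lyz2, Csprs and Sp100, H1f1 and the immunoglobulin genes are uncertain as to the copy.

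Alternatives were a filter on dim probe sets, quantile normalization, centring of arrays, the replicate number as a block, a trended and robust variance prior, array weights, the mean over a gene's probe sets, and each array left out in turn. The fit was tested on simulated data with 41345 probe sets and 200 changed ones per draw over 10 draws. It recovered 56.4% of changes of 1 on the log2 scale, 86.8% at 2, 95.6% at 3 and 98.2% at 4, with 79 false calls over all draws. Its noise was independent between probe sets and the changed ones were taken at random, dim ones included. These shares therefore do not give the power for expressed genes in the real, correlated arrays. Separately, 100 data sets with no group effect were drawn that kept the gene-to-gene correlation of these arrays, to see how many lists the preset correlation then calls. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.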

Results

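Whole mammary tumours from 3 wild-type and 3 Slc6a14 knockout PyMT mice were profiled on 1 array each. Slc6a14 encodes a plasma membrane transporter for neutral and cationic amino acids, and the comparison asks which transcripts differ when PyMT tumours grow without it. Pearson correlations between arrays, taken across probe sets, ran from 0.975 to 0.991. The first principal component held 40.4% of the variance. Wild-type tumours 1 and 2 scored −43.4 and −47.4 on it and the knockout tumours 35.1, 42.0 and 13.5, while wild-type tumour 3 lay between them at 0.18. The array of wild-type tumour 3 correlated most with that of knockout tumour 3 (r = 0.988).

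The deleted gene was lower in each knockout tumour than in each wild-type tumour. Slc6a14 stood at 8.34 ± 0.07 in the wild-type tumours and 5.48 ± 0.36 in the knockout tumours (log2, mean ± SD, n = 3 each), which is 7.28-fold lower. The difference of −2.86 (SE 0.18, 95% interval −3.30 to −2.42) had the smallest p of all probe sets, and its limma adjusted p was 0.0858. Without wild-type tumour 3 or knockout tumour 3 the adjusted p was 0.0286 or 0.0038. Which exons the probe set covers was not analysed here.

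Ighm, Mid1 and Jchain had the largest differences above wild type among the named genes. Ighm, the heavy chain of immunoglobulin M, was 12.3-fold higher in the knockout tumours, at 7.50 ± 0.15 against 11.12 ± 1.34 (log2, n = 3). Its 7 probe sets differed by 0.64 to 3.83, and with 1 array left out the difference of 3.62 ran from 3.07 to 4.37. Jchain, which links immunoglobulin units, was 9.33-fold higher (difference 3.22, SE 0.59, and 2.73 to 3.93 with 1 array left out). Cxcl13, a chemokine that draws B cells, was 3.03-fold higher (difference 1.60, SE 0.25). Mid1, a ubiquitin ligase bound to microtubules, was 11.6-fold higher (difference 3.54, SE 0.39). The matrix proteins Dpt and Prelp were higher by 1.82 and 1.50 on the log2 scale, and a second probe set of Prelp by 0.17. Osr1, a transcription factor of connective tissue progenitors, was higher by 1.89. Mfsd2a, a carrier of lysophospholipids, was higher by 2.08, St8sia6, a sialyltransferase, by 2.04, and Gfpt2, an enzyme of the hexosamine pathway, by 1.64. Sec14l4, Adgrd1 and Lyz1 had differences of 1.67, 1.61 and 1.53.

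After Slc6a14, the named genes with the largest differences below wild type were Strc, Mal, Galnt9, Npl and Krt10. Krt10 and Krt1, the keratin pair of differentiating epidermis, were 3.19-fold and 2.70-fold lower in the knockout tumours (differences −1.67, SE 0.17, and −1.43, SE 0.14). Strc, which encodes stereocilin, was 3.78-fold lower (difference −1.92, SE 0.15, adjusted p = 0.0858). Mal, a protein of apical membrane transport, had a difference of −1.78, Galnt9, which starts O-linked glycan chains, one of −1.77, and Npl, which cleaves sialic acid, one of −1.75. The small nucleolar RNAs Snora73b and Snora73a had differences of −1.64 and −1.47. S100a8, a calcium-binding protein of neutrophils, was lower by a difference of −1.46. Csprs, H1f1, Fstl4 and Htra4 had differences of −1.49, −1.43, −1.33 and −1.32.

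None of these genes passed the threshold: limma called 0 of 41345 probe sets at an adjusted p of 0.05, and the genes above were named by size among those with separate groups. An unadjusted p under 0.05 was found for 3826 probe sets, 1707 higher and 2119 lower in the knockout tumours, where 2067 are given by chance with no effect. The groups did not overlap for 3487 of 22180 genes (15.7%), against 10% by chance. The count of calls rested on which tumours entered. Without wild-type tumour 3 it was 110 (61 higher, 49 lower), among them Mid1, Gfpt2, Strc and Krt1, and without knockout tumour 3 it was 112 (98 higher, 14 lower), among them Ighm, Jchain, Strc and Krt1, with 6 probe sets in both.

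**Figure D1:**
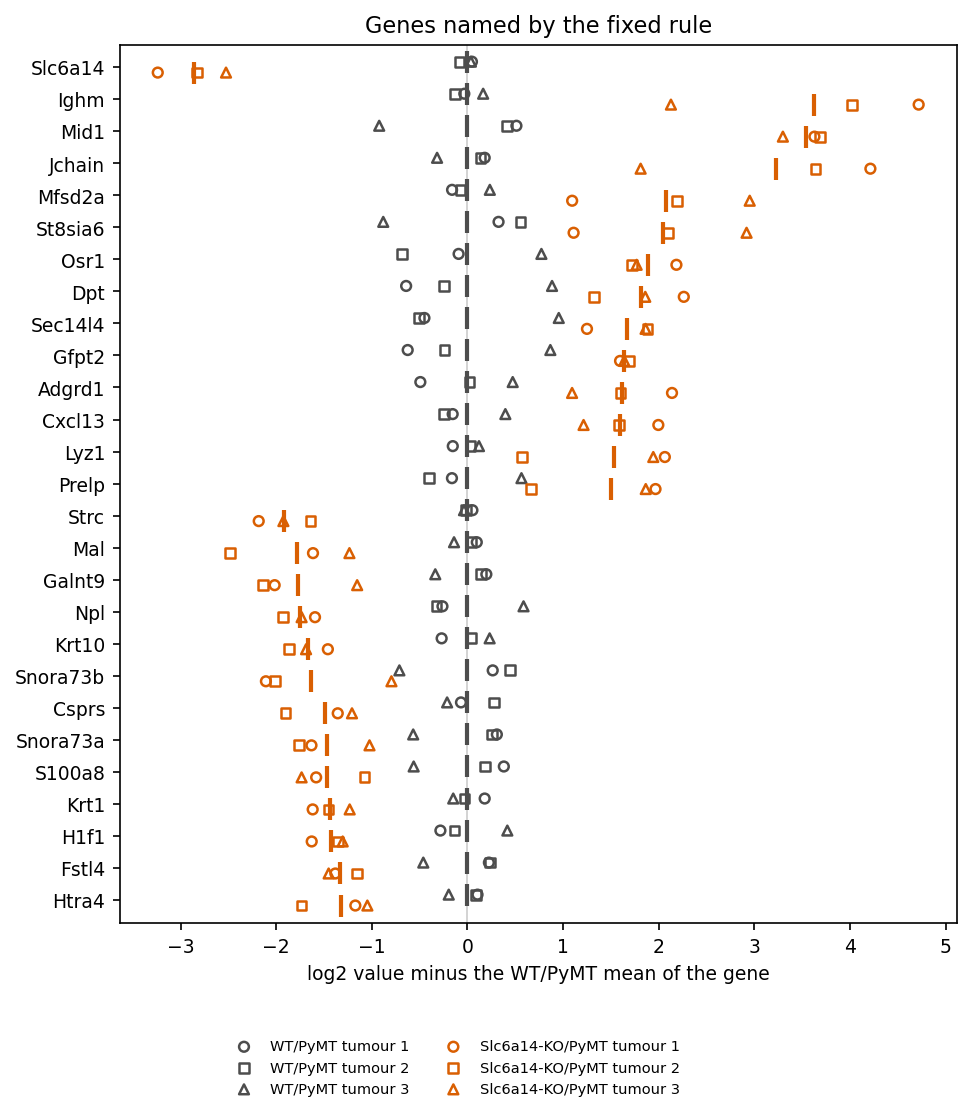
Each row is a gene named by the fixed rule and the horizontal axis is its log2 value minus the wild-type mean of that gene, with 1 symbol per tumour and vertical bars at the group means (n = 3 each). Slc6a14 lies at −2.86 and Ighm, Mid1 and Jchain at 3.62, 3.54 and 3.22, and in each row the symbols of the 2 groups do not overlap.

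Connective tissue genes were higher in the knockout tumours as a group. Of 21 genes of fibroblasts and matrix, 15 were higher and 0 lower at an unadjusted p under 0.05, with a mean difference of 0.81 (1.75-fold). Fibronectin (Fn1) was higher by 1.02 (SE 0.17), the collagens Col5a1 and Col6a1 by 0.73 and 0.78 (0.023 and 0.58 in their second probe sets), and the collagen cross-linking enzyme Lox by 0.93. Among 17 genes of mesenchymal transition and invasion, with a mean of 0.49, 8 were higher and 0 lower, among them the fibronectin receptor subunit Itga5 (0.58), vimentin (Vim, 0.80), tenascin C (Tnc, 1.44) and stromelysin (Mmp3, 1.21). Of 15 basal and myoepithelial genes, with a mean of 0.63, 6 were higher and 0 lower. Those with the smallest p are contractile genes or the oxytocin receptor: Oxtr (1.07), Actg2 (1.45), Tagln (1.08) and Acta2 (0.98).

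These 3 lists passed camera's threshold with the preset correlation (adjusted p = 1.3e-13 for fibroblasts and matrix, 3.8e-08 for mesenchymal transition and 2.1e-04 for basal and myoepithelium), also without each array in turn. With an estimated correlation the adjusted p was 0.538, 0.373 and 0.538. Adjusted over the list alone, 1, 6 and 5 members passed, against 0 in each list adjusted over all probe sets. Wild-type tumour 3 resembled the knockout tumours in these genes. Its fibroblast list mean lay 0.53 above the wild-type mean, against −0.25 and −0.29 in wild-type tumours 1 and 2 and 1.09, 0.80 and 0.55 in the knockout tumours.

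Several immune lists were higher too, mostly through knockout tumour 1. Of 16 genes of B cells, plasma cells and lymph node, 4 were higher and 0 lower, namely Cxcl13, Jchain, the homing receptor Ccr7 (0.69) and the B cell coactivator Pou2af1 (0.84), and all 16 had positive differences (mean 0.56). With dim probe sets left out only Cxcl13, Jchain and Ccr7 remained, with a mean of 1.84. Of 20 macrophage genes 6 were higher and 0 lower (mean 0.14), with Tyrobp (0.40), Lyz2 (0.29), Itgam (0.25) and Cd163 (0.45) first. Of 17 T and NK cell genes 2 were higher, Cd5 (0.27) and Cd4 (0.22), ahead of Cd2 (0.29) and Cd8b1 (0.62), which were 0.15 and 0.26 without knockout tumour 1. The interferon list (mean 0.17) had 1 of 22 genes higher, Ifit3 (0.37), and the class II list (mean 0.28) 1 of 9, H2-Ab1 (0.70, and 0.41 without knockout tumour 1). Knockout tumour 1 had the highest mean in each of these 5 lists, at 0.90 for B and plasma cells, 0.33 for macrophages, 0.60 for T and NK cells, 0.75 for interferon response and 0.64 for class II genes.

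All 5 passed camera with the preset correlation, with adjusted p from 2.0e-06 for B and plasma cells to 0.0468 for class II genes. With an estimated correlation the adjusted p was 0.538 for B and plasma cells and 0.735 for each of the other 4. Adjusted over the list alone, 2 B and plasma cell genes passed (Cxcl13 and Jchain) and 0 in the other 4 lists, against 0 over all probe sets. Without knockout tumour 1 the means of T and NK cells and interferon response turned to −0.010 and −0.11, and those of macrophages and class II genes shrank to 0.051 (adjusted p = 0.0689) and 0.10 (0.508). Without knockout tumour 2 or 3 the means were 0.29 and 0.30 for T and NK cells (0.0011 and 0.0013) and 0.29 and 0.34 for interferon response (0.0013 and 5.1e-05), and without knockout tumour 2 that of class II genes was 0.42 (9.1e-04). Calls also ended without wild-type tumour 3 for T and NK cells (0.122), macrophages (mean 0.091, adjusted p = 0.0525), interferon response (0.049, 0.278) and class II genes (0.0716), and for class II genes without wild-type tumour 1 (0.103) or 2 (0.116). The neutrophil list did not pass (adjusted p = 0.812). S100a8 was its only member to pass adjusted over the list alone, Lcn2, Il1r2 and S100a9 differed by 0.31, 0.21 (0.13 and 0.14 without wild-type tumour 1 and knockout tumour 2) and −0.18 (−0.28 without wild-type tumour 2 or knockout tumour 1), and its mean of −0.040 and median of 0.012 differ in sign.

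Fat, handling and muscle genes varied between the knockout tumours. Of 17 adipocyte genes, with a mean of 0.64, 2 were higher and 0 lower, Retn (1.44) and Pparg (0.83), ahead of Pck1 (0.76) and Plin1 (0.94). Of 20 immediate early genes, which respond within minutes to stimulation or dissection, 6 were higher and 0 lower (mean 0.52), led by Egr1 (1.21), Zfp36 (0.68), Fos (1.36) and Jun (0.23). Knockout tumour 1 stood at 1.38 and 1.10 in these lists, against 0.16 and 0.41 in knockout tumour 2 and 0.38 and 0.065 in knockout tumour 3. Of 18 skeletal muscle genes 0 had an unadjusted p under 0.05. Pvalb, Eno3, Casq1 and Mb differed by 0.28, 0.34, 0.21 and −0.38, and knockout tumour 3 had the highest mean of that list (0.46).

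Adjusted p with the preset correlation was 1.0e-05 for adipocytes, 8.7e-06 for immediate early genes and 0.0257 for skeletal muscle, and with an estimated correlation 0.735, 0.579 and 0.735. No member passed adjusted over the list alone. Without knockout tumour 1 the means of adipocytes and immediate early genes were 0.27 and 0.23, and Pparg, Pck1, Plin1, Zfp36 and Fos were 0.51, 0.36, 0.49, 0.43 and 0.90. The muscle call ended without wild-type tumour 1, 2 or 3 (0.0611, 0.0704 and 0.0504), and without knockout tumour 1 its mean was 0.23 (0.0032). Without knockout tumour 3 its mean was −0.0091 and Pvalb, Eno3 and Casq1 were 0.18, 0.18 and 0.11, and without wild-type tumour 2 Mb was −0.25. The endothelial list did not pass (mean 0.11, adjusted p = 0.062), with Robo4 (0.30), Tek (0.54), Erg (0.33) and Ptprb (0.37) first. Without knockout tumour 1 these were 0.16, 0.32, 0.087 and 0.12, and without knockout tumour 2 Erg was 0.49 and Ptprb 0.61. For the list, without knockout tumour 1 its mean was −0.055 and without knockout tumour 2 it was 0.25 (adjusted p = 7.5e-05).

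Genes of amino acid supply and growth differed by small amounts. Among 34 other amino acid transporters, 2 were higher and 0 lower, the taurine carrier Slc6a6 (0.40, SE 0.09) and the glutamine carrier Slc1a5 (0.58, SE 0.15, with 0.070 in its second probe set), ahead of Slc1a3 (1.03, and 0.53 without knockout tumour 2) and Slc36a1 (0.21), with a list mean of 0.16. Targets of ATF4, the transcription factor induced by amino acid shortage, had a mean of −0.11. Of these 27 genes 2 were lower, the serine synthesis enzyme Psph (−0.43) and the mTORC1 inhibitor Ddit4 (−0.90), ahead of Slc7a11 (−0.22) and Vldlr (−0.26, and −0.17 without knockout tumour 2). Of 18 aminoacyl-tRNA synthetases 3 were lower, Lars (−0.41), Eprs (−0.29) and Qars (−0.24), ahead of Hars (−0.22), with a mean of −0.14. Of 21 genes of ribosome biogenesis and MYC 5 were lower, among them Gnl3 (−0.37), Ncl (−0.27), Nop58 (−0.27) and Wdr12 (−0.31), with a mean of −0.11. In the cell cycle list (mean −0.13) only Mcm2 (−0.41) of 33 genes was lower at that level, ahead of Ccne1 (−0.31), Pcna (−0.21) and Cenpf (−0.28, and −0.17 without knockout tumour 3), and 0 genes were higher in these 4 lists.

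Adjusted p with the preset correlation was 0.0384 for transporters, 0.0375 for ATF4 targets, 0.0038 for synthetases, 0.0153 for ribosome biogenesis and 0.0257 for the cell cycle. With an estimated correlation the adjusted p was 0.538 for transporters and 0.735 for each of the other 4. No member passed adjusted over the list alone or over all probe sets. Each call ended without at least 1 array. Transporters lost it without wild-type tumour 2 or 3 (0.0704 and 0.0636) or knockout tumour 2 or 3 (0.164 and 0.0588). ATF4 targets lost it without wild-type tumour 1 (mean −0.048, adjusted p = 0.374) or 2 (−0.071, 0.149) or knockout tumour 1 or 3 (0.0689 and 0.0626), and without wild-type tumour 3 their mean was −0.22 (9.3e-04). Synthetases lost it without knockout tumour 3 (0.0637), and ribosome biogenesis without wild-type tumour 1 (mean −0.070, adjusted p = 0.0951) or knockout tumour 1 (0.122). The cell cycle list lost it without wild-type tumour 1 or 2 (0.0851 and 0.12) or knockout tumour 1 or 3 (0.143 and 0.967), in the last case with a mean of −0.012, and without knockout tumour 2 its mean was −0.28 (6.6e-09). Knockout tumour 2 had a higher mean of that list (0.15) than each wild-type tumour (0.051, 0.077 and −0.13), against −0.18 and −0.38 in knockout tumours 1 and 3.

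The lists of metabolism, milk and luminal epithelium did not pass. Hypoxia and glycolysis genes had a mean of −0.22 (adjusted p = 0.062). Adjusted over the list alone 3 of its 21 members passed, the aldolase Aldoc (0.71), the phosphofructokinase Pfkl (−0.44) and the pyruvate dehydrogenase kinase Pdk1 (−0.64, with −0.26 in its second probe set). Adm came next (−1.02, and −0.66 without knockout tumour 2). Without wild-type tumour 3 the list mean was −0.41 (adjusted p = 6.6e-05). Without wild-type tumour 1 or 2 it was −0.12 or −0.13 (0.313 and 0.225). Fatty acid synthesis genes (mean −0.073, adjusted p = 0.273) went both ways, with Elovl6 (0.75) and Dgat2 (1.07) higher, Scd1 (−0.54) lower and Fads1 (0.45, and 0.29 without wild-type tumour 3) higher at an unadjusted p under 0.05. Their mean ran from −0.16 without knockout tumour 1 to −0.014 without knockout tumour 3 and did not pass in either case (0.0689 and 0.709). Sterol biosynthesis genes had a mean of 0.063 (adjusted p = 0.172), with Pmvk (−0.35), Msmo1 (0.28), Fdps (0.36) and Srebf2 (0.16) first. Without knockout tumour 2 Msmo1 was 0.18, Fdps 0.10 and Srebf2 0.10, while Msmo1 was 0.18 without wild-type tumour 3, Srebf2 0.062 without wild-type tumour 2 and Fdps 0.55 without knockout tumour 3. Without wild-type tumour 1 or 3 that mean was 0.10 or 0.0099, without knockout tumour 2 it was −0.043, and without knockout tumour 3 it was 0.18 (adjusted p = 0.0014). Milk and secretory genes had a mean of −0.26 (adjusted p = 0.148), with Cel (−1.08), Glycam1 (1.40), Ltf (−0.74, and −0.34 without knockout tumour 2) and Plin2 (−0.32, and −0.19 without wild-type tumour 1) first, and the list passed without wild-type tumour 3 (mean −0.51, adjusted p = 0.006) or knockout tumour 3 (−0.40, 0.0375). Without knockout tumour 2 its mean was −0.0043 (0.785), and without wild-type tumour 1 or 2 it was −0.13 (0.352 and 0.482). Luminal epithelial genes (adjusted p = 0.371) had a mean of 0.050 and a median of −0.11, with the claudins Cldn4 (−0.95) and Cldn3 (−0.49), Spdef (−1.03) and Erbb3 (−0.45, and −0.28 without knockout tumour 2) first. Their mean was −0.011 without wild-type tumour 2, −5.6e-04 without knockout tumour 1 and −0.14 without knockout tumour 3.

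Autophagy and lysosome genes had a mean of −0.040 (adjusted p = 0.706), with Gaa (0.49), Atg14 (−0.37), Sqstm1 (0.28) and Ctsl (0.23) first. Genes of arginine, nitric oxide and polyamines had a mean of 0.032 and a median of −0.014 (adjusted p = 0.956). Of these 17 genes 4 were lower, among them Gatm (−1.06), Ddah2 (−0.52) and Oaz2 (−0.24, with −0.063 in its second probe set). Arg2 (1.07, and 0.61 without knockout tumour 3) was higher. Clock genes had a mean of −0.0018 (adjusted p = 0.478), with Per3 (−0.58), Cry2 (−0.32), Clock (0.31) and Nr1d2 (−0.43, and −0.20 without knockout tumour 2) first, and Per3 alone passed adjusted over the list alone. Xist stood at 12.97 ± 0.03 in wild-type and 12.86 ± 0.23 in knockout tumours. The Y-linked genes Kdm5d, Eif2s3y and Uty stood between 3.62 and 4.42 in both groups, and the sex marker list had an adjusted p of 0.387. Among 41 measured neighbours of Slc6a14, 5 were higher and 4 lower at an unadjusted p under 0.05, with a mean of 0.031, a median of −0.061, a camera p of 0.573, and a fry p of 0.0072 for change in either direction. Over all genes, 9.53% had an unadjusted p under 0.05. Among the neighbours, Timp1, an inhibitor of matrix metalloproteinases, was higher by 0.80 (SE 0.14) and alone passed adjusted over the list alone, and Ndufb11, Slx and Maob differed by −0.54, −0.51 and 1.57.

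Of the 27 lists, 16 passed with the preset correlation, 12 higher and 4 lower in the knockout tumours, and 0 passed with an estimated correlation. Fry's test of 1 direction passed 0 lists, with an unadjusted p under 0.05 for fibroblasts and matrix (0.0473) and mesenchymal transition (0.0054). Its test of change in either direction passed 4 lists, mesenchymal transition, macrophages, autophagy and lysosome, and the circadian clock. In 100 simulated data sets with no group effect and the correlation of these arrays, the preset correlation called a median of 9.5 lists and at most 18, with 16 or more in 4 of them. A mean as far from 0 as the observed one occurred in 0 of these 100 for fibroblasts and matrix, mesenchymal transition, basal and myoepithelium, B and plasma cells, and amino acid transporters. For the other called lists it occurred in 5 (synthetases), 9 (ribosome biogenesis, and immediate early genes), 13 (adipocytes, and class II genes), 22 (macrophages), 25 (ATF4 targets), 37 (T and NK cells), 40 (skeletal muscle), 47 (cell cycle) and 61 (interferon response). These draws took the spread estimated from the 6 arrays as known, so 0 of 100 does not give a chance under 1 in 100. Fry's unadjusted p for 1 direction was 0.0853 for basal and myoepithelium, 0.0598 for B and plasma cells and 0.0547 for amino acid transporters.

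**Figure D2:**
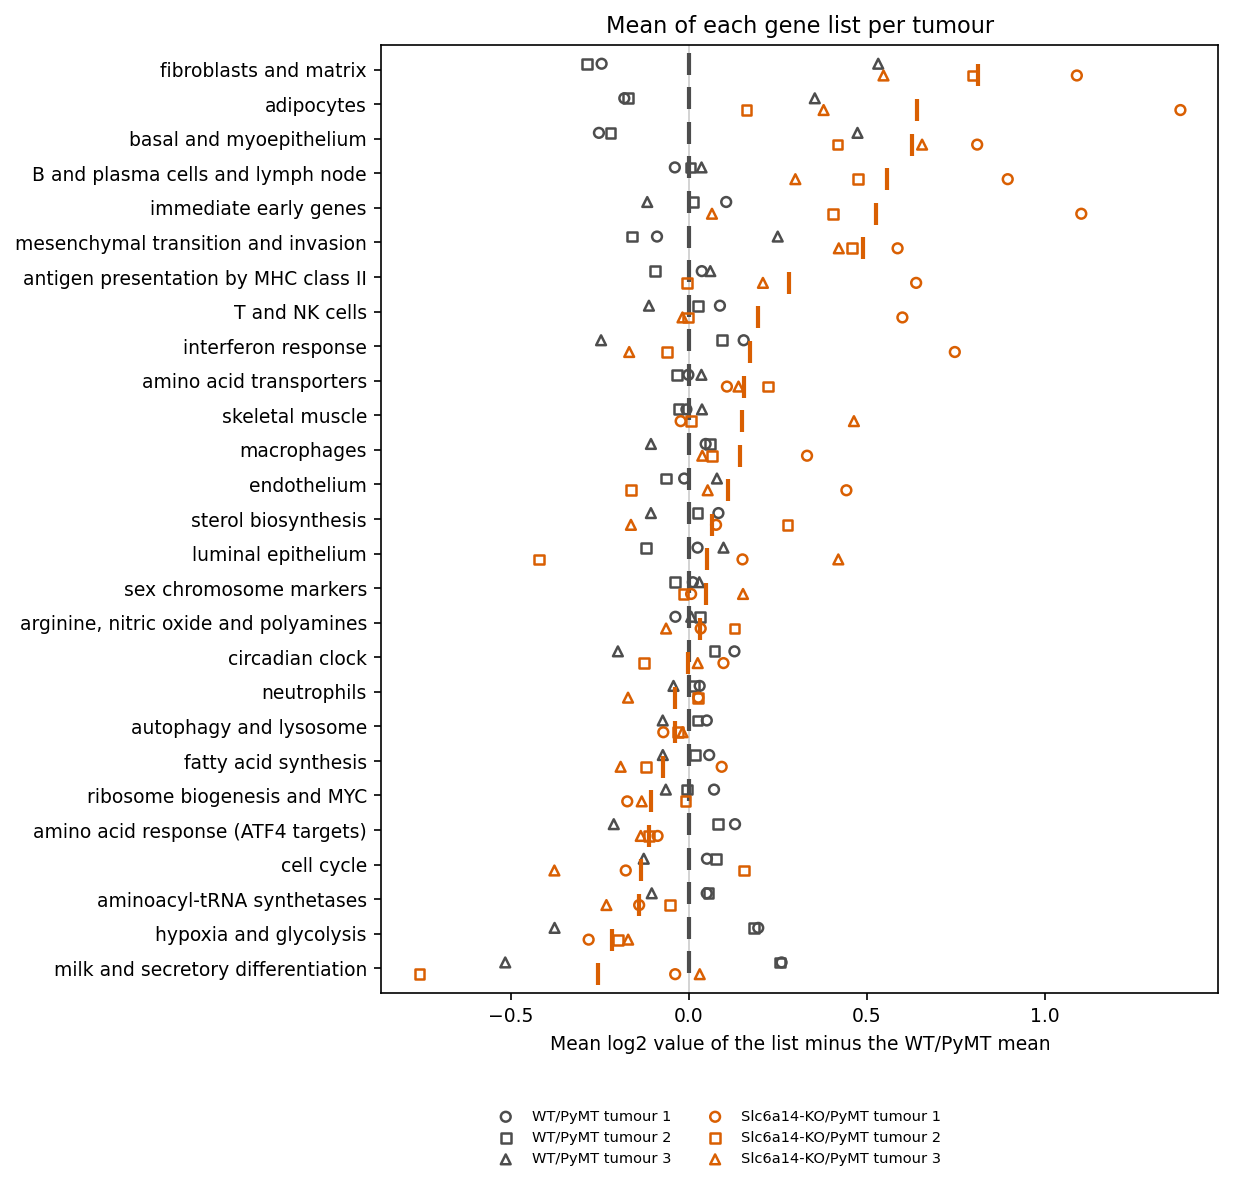
Each row is a gene list fixed beforehand and the horizontal axis is its mean log2 value in a tumour minus the wild-type mean, with 1 symbol per tumour and vertical bars at the group means (n = 3 each). Wild-type tumour 3 lies at 0.53 for fibroblasts and matrix, away from −0.25 and −0.29 in the other wild-type tumours, and knockout tumour 1 lies at 1.38 for adipocytes and 1.10 for immediate early genes.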

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

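The single-gene restriction, and fry as an alternative to camera, were added after seeing the data, and the other alternatives before. The count of 0 called probe sets held under all 7 other planned settings and ranged from 0 to 112 with 1 array left out. With only single-gene probe sets tested it was 1 (Slc6a14, difference −2.86, limma adjusted p = 0.0372). There fewer tests are adjusted for, and the variance prior is estimated again from the probe sets kept. Slc6a14 was lower under each setting, between −3.03 and −2.68 with 1 array left out, and its adjusted p then ran from 0.0038 to 0.498. The number of called lists ranged from 9 to 16 with 1 array left out, and was 0 with an estimated correlation, 0 with fry's test of 1 direction and 4 with its test of change in either direction. Of the 16 called lists, 6 kept the call without each array in turn and under the 7 other settings with the preset correlation. With dim probe sets left out 11 lists passed: calls ended for ATF4 targets (adjusted p = 0.374), synthetases (0.0526), cell cycle (0.198), ribosome biogenesis (0.147), skeletal muscle (0.198) and T and NK cells (0.476), and endothelium passed (0.0381). Quantile normalization ended those of ATF4 targets and cell cycle (0.0532 each), centring (0.0524) and the mean over probe sets (0.051) that of ATF4 targets, and array weights that of interferon response (0.0573). Hypoxia and glycolysis passed with the trended prior (0.0432), array weights (0.0233) and the mean over probe sets (0.0442), and endothelium with centring (0.039) and array weights (0.0351). The X-linked neighbours of Slc6a14 passed camera under no setting, but camera tests a shift one way and can miss neighbours that changed in both directions. Directions turned for several lists, the called T and NK cells, interferon response and skeletal muscle among them. With dim probe sets left out, luminal epithelium had a mean of −0.0038 and the circadian clock 0.016. The clock was at 0.013 after quantile normalization and 0.0033 with the mean over probe sets. With 1 array left out the means ran from −0.043 to 0.18 for sterol biosynthesis, −0.14 to 0.28 for luminal epithelium, −0.0091 to 0.23 for skeletal muscle, −0.010 to 0.30 for T and NK cells, −0.073 to 0.026 for neutrophils, −0.055 to 0.25 for endothelium, −0.11 to 0.34 for interferon response, −0.016 to 0.080 for arginine, −0.10 to 0.062 for the circadian clock, and −0.0046 to 0.079 for sex markers. Xist ran from −0.21 to 0.020 and Uty from −0.047 to 0.012. The cause was not tested. Same-numbered tumours deviated from their group means with correlations of 0.24, −0.012 and 0.031. Not every array correlated best with its own number in the other group. However, the second principal component, with 21.1% of the variance, scored tumour 1 highest and tumour 3 lowest in both groups. Wild-type and knockout tumours 3 scored −37.3 and −23.7 on it. Whether same-numbered tumours share a batch therefore stays open. With the replicate number as a block the count of called probe sets was 0, the count of lists 16, and the adjusted p of Slc6a14 0.41. Dim genes sit near the array floor, where differences can be compressed, which was not measured here.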

Other observations

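Apart from the plasma cell, skin, genome segment and list-split tests, the tests below were chosen only after the result was seen, and so were the lists of immunoglobulin genes, small nucleolar RNAs, cornified epidermis, resting B cells and plasma cells. Immunoglobulin transcripts were higher in the knockout tumours across the family. Of 36 immunoglobulin probe sets 36 had positive differences, 25 of them with an unadjusted p under 0.05, and the median was 2.27 on the log2 scale. Knockout tumours 1, 2 and 3 lay 3.24, 2.64 and 0.90 above the wild-type mean. Among the 21 immunoglobulin genes with probe sets of their own, Igkv4-59 was higher by 3.38 and Igkj1 by 3.56, and the median was 2.24 (camera adjusted p = 6.5e-18 with the preset correlation, adjusted p = 0.157 with an estimated correlation).

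Small nucleolar RNAs, which guide chemical modification of ribosomal RNA, were lower: 59 of 73 had negative differences, with 22 lower and 2 higher at an unadjusted p under 0.05 and a median of −0.18. Snora75 differed by −0.70 and Snord17 by −0.54, while Snora23 was higher by 0.77. Their camera adjusted p was 6.7e-07 with the preset correlation, and the adjusted p was 0.157 with an estimated correlation. The list holds Snora73a and Snora73b, named above for their falls, so this p is partly a retest of them. The adjustment in this section runs only over the lists added after the result was seen. Of 30 cornified epidermis genes other than Krt1 and Krt10, 28 had negative differences and 7 were lower at an unadjusted p under 0.05, among them Flg (−0.65), Dsc1 (−0.98) and Calml3 (−0.99), with an adjusted p of 4.5e-06 and an adjusted p of 0.157 with an estimated correlation. Wild-type tumour 3 stood with the knockout tumours in the mean of these genes, at −0.33 against −0.40, −0.38 and −0.36. Wild-type tumours 1 and 2 stood at 0.19 and 0.14. Dsg3 (−1.29) and Klk7 (−1.76) of this list were among the genes called lower without wild-type tumour 3. Skin in the wild-type samples was tested through the median of that list, predicted beforehand at −0.5 or below. It was −0.23 (95% interval over members −0.56 to −0.14), which meets neither that prediction nor its opposite. In a split that was not part of the prediction, the 12 members bright in some array had a median of −0.64 (−0.95 to −0.28). The 18 members dim in all arrays had a median of −0.14. Skin stays open. Krt10 was highest in wild-type tumour 3 (7.59, against 7.09 and 7.40 in tumours 1 and 2 and 5.49 to 5.90 in the knockout tumours), and Krt1 stood there at 6.65, against 5.18 to 5.57 in the knockout tumours, so the mean of the other epidermal genes does not follow these keratins in that tumour.

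The higher immunoglobulin and J chain transcripts were weighed first. Strain differences in immunoglobulin segments do not reach Jchain, which has no segments and differed by 3.22 (95% interval 1.79 to 4.65). However, Jchain was named by a rule that required an unadjusted p under 0.01. An interval above no change was thus fixed in advance, and the test cannot decide. For the segment genes strain differences stay open. Lymph node tissue stays open: resting B cell markers had a median difference of 0.20 (0.086 to 0.53) over all knockout tumours, under the 1 set for it, and, split after the values per array were seen, 0.60 (0.30 to 1.08) in knockout tumour 1, where T cell markers were higher as well (median 0.56) and some may be present. In knockout tumours 2 and 3 the median was 0.049 (−0.019 to 0.21). In knockout tumour 2 alone it was 0.090, where immunoglobulin probe sets lay 2.64 above the wild-type mean, against 3.24 in knockout tumour 1. However, 13 of the 15 markers were dim in wild-type tumours, where differences can be compressed. These markers still rose in knockout tumour 1, so being dim does not hide every gain, and a smaller share of lymph node is not excluded. More plasma cells, the biological explanation, stays open too. The other plasma cell markers had a median of 0.074 (−0.077 to 0.21), below the 0.5 set beforehand. That bound was set aside on a condition added after this was seen. In wild-type tumours 4 of the 10 were dim (Tnfrsf17 at 4.01) and 2 high (Derl3 at 8.94 and Xbp1 at 12.86). At such levels a small share can be hidden, which was not measured. The other 4 went both ways (Slamf7 0.29, Prdm1 0.095, Fkbp11 −0.016, Sdc1 −0.29).

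The higher connective tissue and smooth muscle genes were weighed second. A lower share of tumour epithelium as the whole cause would raise all other cell types alike. The fibroblast mean exceeded the endothelial mean by 0.70 (95% interval over members 0.54 to 0.85), which meets the bound set against it. That interval measures the spread over genes and not over tumours. Wild-type tumour 3 stood at 0.53 in the fibroblast list and 0.079 in the endothelial list, against 0.55 and 0.053 in knockout tumour 3. With 1 array left out the fibroblast mean was at least 0.67 and the endothelial mean at most 0.25. These values argue against a lower share of epithelium as the whole cause, raising all other cell types alike. As part of the cause it stays open: the luminal list had a mean of 0.050 and a median of −0.11. A single array carrying the higher fibroblast genes is argued against by the mean difference of that list, which stayed between 0.67 and 1.08 without each array in turn. The separation of the groups was narrow, with knockout tumour 3 at 0.546 and wild-type tumour 3 at 0.532. Of its 21 members, 8 had separate groups. Which part of each tumour was sampled is not given in the sources used here and could matter, since wild-type tumour 3 resembled the knockout tumours, and an effect of the deletion on the stroma stays open as a hypothesis.

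The large differences of Mid1, Sp100 (−0.94), Csprs, Strc and Cep112 (0.98) were weighed last, Sp100 and Cep112 having been singled out after their values were seen. Genome segments of another strain may hold several affected neighbours, and of the 100 genes with the smallest p, immunoglobulins left out and 1 gene counted per name family, 10 had another within 1 Mb, against a median of 11 in random draws (share with as many 0.673). Without the family rule it was 14 against 13 (0.484). These counts meet the bound set beforehand, no more neighbours than chance gives, but that bound was too loose for 5 genes, since the random draws reach 8 above their median at the 95th percentile, a spread computed after the result was seen. Csprs lies near Sp100 and Cep112 near Cep112it, pairs that can share probes or overlap and so cannot decide on a segment. Gm7609 (−1.43) and LOC100039029 (−0.71), also on chromosome 1 and among the genes with such a neighbour, were lower too. Whether they share probes was not tested. Around Slc6a14 itself, 5 of 41 neighbours were higher and 4 lower at an unadjusted p under 0.05, against 9.53% of all genes. Fry's p for change in either direction was 0.0072 there, and camera's p for a shift one way 0.573. Strain segments stay open, and a biological explanation was not tested.

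The split of the 6 tumours by genotype gave 3826 probe sets at an unadjusted p under 0.05, and the highest of the other splits, wild-type tumours 1 and 2 with knockout tumour 1, gave 3670. For called gene lists the real split gave 16, and the highest of the others, wild-type tumours 1 and 2 with knockout tumour 2, gave 15. In each case 1 of the 10 splits, the real one, gave a count as large, and 10 splits are too few for a share under 0.05.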
